A study of Homo sapiens with 28 samples.

How the data were processed

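Open chromatin was measured by ATAC-seq, in which a transposase cuts and tags accessible DNA, in AN3CA, an established human endometrial carcinoma cell line. The cells expressed an empty vector or a form of ARID1A or ARID1B, the large ARID-domain subunits that are alternatives to each other in the canonical BAF (cBAF) chromatin remodeling complex. The title of the series and the titles of the samples name ATAC-seq, while the design text of the series describes CUT&Tag of BAF subunits and a histone mark. The lists were taken as ATAC-seq, as the titles have it. The 28 libraries fall into 13 groups by their titles. Empty_vector has 4 libraries and each of the other 12 groups has 2. Per the labels' protocols, tagmented DNA was purified and amplified with a limited number of PCR cycles. The labels do not say whether the replicates came from separate cultures, so the p-values below measure the spread between these samples, which may be technical.

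The genotype label and the title disagree in 10 libraries of 5 constructs (ARID1A_AQGscramC1C2, ARID1A_Y42S, ARID1B_A457_G461del, ARID1B_Block13del and ARID1B_Block9del). Their genotype label names the empty vector control while their title names a construct. They were grouped by title, and in all 10 deposited lists the names of the peaks also carry the construct of the title. The meaning of the construct names beyond the labels was not assumed.

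Each library has 1 peak list, so peaks were called per sample. Per the submitters' processing notes, the tools were bcl2fastq, Bowtie2, Picard 2.8.0, SAMtools 0.1.19 and MACS2, and the genome build was hg19. The options of the peak caller, the control and the handling of the cut-site offset are not given in the sources used here. In the deposited lists each peak has a fold enrichment (a ratio over the background that the caller estimated), a -log10 p-value, a -log10 q-value and a score. The smallest -log10 q-value of a deposited list lay between 3.00 and 3.03 in all 28 libraries, so the lists share 1 threshold. The deposited score equals 10 times the -log10 q-value, rounded down, except in 59 of 1247388 peaks. These values are the authors' own and were used to rank and describe peaks within a list. No read counts are part of these lists, so the sequencing depth is unknown. The length of a list depends on depth as well as on chromatin, and a list gives no signal where no peak was called.

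The names of the peaks carry a date code, which divides the libraries into 6 sequencing or processing runs, called A to F here. Runs A and B hold 1 library each of Empty_vector, ARID1A_WT, ARID1A_DBDmut, ARID1A_delIDR1 and ARID1A_CBR. Run C holds 2 libraries each of Empty_vector, ARID1B_WT and ARID1B_S320_G327del. Run D holds ARID1A_DDX4 alone, run F holds ARID1A_AQGscramC1C2 alone, and run E holds the 4 remaining constructs. Runs D, E and F have no empty vector and no wild-type library, so their constructs have no control of the same run. In runs D and F, with 1 construct each, the construct and the run cannot be told apart.

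To keep list length from setting the calls, each list was restricted to chromosomes 1 to 22 and X and trimmed to its 19433 most significant peaks, the length of the shortest list (ARID1A_Y42S 2). Peaks were ranked by -log10 p-value within their own list. Overlapping peaks of all trimmed lists were merged, and merged regions called in at least 2 libraries were kept, which gave 32972 regions. A library called a region if one of its peaks overlapped it by at least 1 bp. A region called in all 4 wild-type libraries (ARID1A_WT and ARID1B_WT) and in none of the 4 empty vector libraries is named gained, and the opposite is named lost. Recovery is the percent of gained regions that a library calls. It was averaged over sets that leave out each wild-type library in turn, and a wild-type library was scored only on the set made without it. The other library of the same construct still helped to choose that set, which favours the wild type over the altered constructs. The background was measured in the same way in each empty vector library, on the set made without that library. The other empty vector libraries still helped to choose that set, which lowers the background.

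Differences in recovery were tested with exact permutation tests, two-sided. These tests and their sample sizes count libraries, so replicates of a construct were treated as independent. The F statistic across the 12 constructs other than Empty_vector was tested with 100000 permutations, and so was the similarity of replicates (one-sided). Similarity was the Jaccard index, the regions called by both libraries divided by those called by either. Adjustment for multiple tests followed Benjamini and Hochberg. Shares of regions per library carry 95% Wilson intervals, at most 2.25 percentage points to either side. These cover counting error only, and neighbouring regions are not independent. The regions named in the text are the 15 gained and 5 lost regions with the best mean rank in the lists that call them, a rule fixed before the data were examined, as were the tests above and most alternatives. Peaks of these lists were not assigned to genes, promoters, motifs or the construct sequences, since no annotation or sequence of hg19 was used here.

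Alternatives were the whole lists as deposited, a list 9716 peaks long, an equal covered length (14.0 Mb), ranking by fold enrichment, a 50% overlap, windows of 500 bp, leaving out each wild-type and empty vector library, and leaving out the 10 libraries with conflicting labels. The procedure was tested on simulated lists. With no effect in 95412 simulated regions, 16 were called gained and 7 lost. With 1000 planted gains, 99.7% were recovered and 44 regions were called lost. A simulated variant with a true recovery of 50.0% was measured at 50.4%. The planted gains were given strengths among the highest simulated values, and noise was independent between libraries, without differences between runs. The simulation thus checks the procedure on strong gains and does not show how weak gains or run differences fare. Scripts ran in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.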

Results

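Chromatin accessibility was profiled in AN3CA endometrial carcinoma cells that expressed an empty vector, wild-type ARID1A or ARID1B, or altered forms of either protein. The series title concerns local condensation of the cBAF remodeler governed by ARID1A and ARID1B. Per the labels, ARID1A_CBR and ARID1A_delIDR1 are truncations, ARID1A_DBDmut carries a mutated ARID domain, and ARID1A_DDX4 is a hybrid with the intrinsically disordered region of DDX4. ARID1A_AQGscramC1C2, ARID1A_Y42S and the ARID1B deletions are named as in the titles.

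The deposited lists held from 19489 peaks (ARID1A_Y42S 2) to 76589 peaks (ARID1A_WT 1). Lists were long with the wild-type proteins, at 69340 ± 10252 peaks for ARID1A_WT (SD, n = 2) and 61678 ± 2618 for ARID1B_WT (SD, n = 2). Empty_vector had 36935 ± 12313 peaks (SD, n = 4), and its libraries differed by run, with 45286 and 49528 peaks in runs A and B and 24573 and 28353 in run C. ARID1A_DDX4 and ARID1A_Y42S had the shortest lists, at 22397 ± 1753 and 24186 ± 6643 peaks (SD, n = 2 each). Read depth is unknown, so these lengths were not compared by a test.

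**Figure D1:**
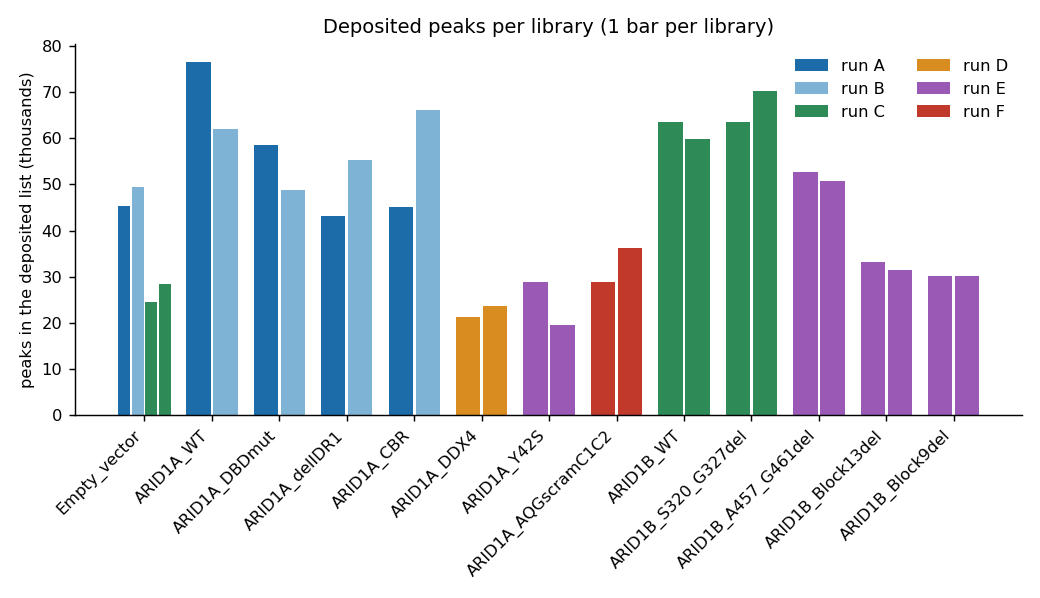
Number of peaks in the deposited list of each library (vertical axis, peaks divided by 1000), 1 bar per library, grouped by construct and coloured by run. The lists range from 19489 to 76589 peaks, and the Empty_vector libraries of run C are shorter than those of runs A and B.

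Libraries of the same construct called similar regions. In lists of equal length, the mean Jaccard index was 0.812 between libraries of a construct and 0.682 between constructs, a difference of 0.130 (permutation test, one-sided, p = 1e-05, the smallest that 100000 permutations can give). Except for Empty_vector and the constructs of runs A and B, the libraries of a construct share 1 run, and the permutation ignored runs. The test therefore cannot part the construct from the run. Empty_vector libraries had a mean index of 0.812 with each other (range 0.779 to 0.873). The mean index with Empty_vector lay within that range for ARID1A_AQGscramC1C2 (0.818) and ARID1B_Block9del (0.801), and under it for all others, such as ARID1A_Y42S (0.772), ARID1A_DDX4 (0.770), ARID1B_Block13del (0.762), ARID1A_CBR (0.757) and ARID1A_DBDmut (0.752).

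The first question was which sites open or close when a wild-type ARID1 protein is expressed. All 4 wild-type libraries called 1905 regions that no empty vector library called, 5.78% of the 32972 regions, with a median width of 974 bp. In the opposite direction 750 regions were lost, with a median width of 844 bp, and 11502 regions were called in all 8 libraries. Among the 35 ways to split these 8 libraries into 4 and 4, the real split alone gave counts as large in either direction. Its share, 0.0286, is the smallest that these splits can give. Within runs, both ARID1A_WT libraries called 3031 regions absent from the Empty_vector lists of runs A and B, against 2278 in the opposite direction. Both ARID1B_WT libraries called 4143 regions absent from the Empty_vector lists of run C, against 3106. The Empty_vector libraries of runs A and B differed from those of run C by 950 and 831 regions.

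The counts depended on the length of the lists. In the whole lists as deposited, 17400 regions were gained and 79 were lost. The Empty_vector libraries of runs A and B already differed from those of run C by 13083 and 50 regions in the whole lists. With the 9716 most significant peaks of each list 396 were gained and 119 lost. At an equal covered length 558 were gained and 89 lost, and with a 50% overlap the lost count was 332. When only peaks that overlap an empty vector peak were ranked, 910 regions were gained and 204 were lost. Of the 1905 gained regions, 1372 (72.0%) were in no empty vector list even at full length. Of the 750 lost regions, 620 (82.7%) were called by all 4 wild-type libraries at full length and 6 by none, so most lost regions stayed open and ranked lower.

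The gained regions with the best ranks lay on several chromosomes (hg19) and were 730 to 1620 bp wide. The first was at chromosome 5, 141289387 to 141290345, with a mean rank of 852 of 19433 peaks in the wild-type lists and a fold enrichment of 7.21 to 8.94 over the caller's background in those 4 lists. A 1620 bp region at chromosome 6, 15504299 to 15505918, had a mean rank of 853 and a fold of 4.70 to 5.38. Neither was in any empty vector list at full length. The next regions were at chromosome 8, 81279030 to 81280190, chromosome 7, 101170903 to 101171848, and chromosome 1, 17858059 to 17859000. The chromosome 8 region was called by all 20 libraries of altered constructs and, at full length, by all 4 empty vector libraries, so its gain is one of rank. Of the 15 gained regions with the best ranks, 6 were in at least 1 empty vector list at full length. Both libraries of ARID1A_DBDmut, ARID1A_delIDR1, ARID1B_S320_G327del, ARID1B_A457_G461del and ARID1B_Block13del called all 15. Both ARID1A_CBR libraries called 10 of them, ARID1A_DDX4 and ARID1A_AQGscramC1C2 called 3, and ARID1A_Y42S and ARID1B_Block9del called 2.

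Lost regions ranked lower in the lists that call them than gained ones, with a median of mean ranks of 15678 against 11065. The first lay at chromosome 10, 73025390 to 73026685, with a mean rank of 4132 in the empty vector lists, and the next at chromosome 8, 129440114 to 129442354, with a mean rank of 4500. All 4 wild-type libraries called both at full length. The region at chromosome 17, 46132734 to 46133659, was called by 2 wild-type libraries at full length.

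The regions gained with the wild-type proteins overlapped. ARID1A_WT gained 2874 regions against all 4 empty vector libraries and ARID1B_WT gained 4006, with 1905 in common. Independent lists among the 10141 regions that no empty vector library called would share 1135. Simulated unchanged libraries against the same controls shared 1.12 on average, but their first set held only 101 regions on average. They therefore give no expected overlap for sets of the real size. With separate controls for each protein, the sets held 3031 and 4143 regions and shared the same 1905 by definition, so splitting the controls gives no further check. Another 538 regions were called in both ARID1A_WT libraries and in no ARID1B_WT or empty vector library, but both ARID1B_WT libraries called 96.1% of them at full length. Of the 1525 regions found in the same way for ARID1B_WT, both ARID1A_WT libraries called 97.8% at full length.

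The next question was how much of this gain each altered protein retained. Wild-type libraries recovered 88.4% ± 1.72 of the gained regions (SD, n = 4), and the background in Empty_vector was 1.09% ± 0.275 (SD, n = 4). The sets favour the wild type, as the replicate of a scored library helped to choose the regions. The background is lowered in a similar way, as the other Empty_vector libraries helped to choose its sets. On the 4006 regions gained with ARID1B_WT, ARID1A_WT called 54.7% ± 0.106, ARID1B_A457_G461del 67.5% ± 0.865 and ARID1A_DBDmut, the highest ARID1A variant, 24.3% ± 0.812 (SD, n = 2 each). On the 2874 of ARID1A_WT, ARID1B_WT called 73.8% ± 0.172, ARID1B_A457_G461del 63.8% ± 0.541 and ARID1A_DBDmut 43.65% ± 2.78 (SD, n = 2 each). Recovery differed between the 12 constructs (F = 1531, permutation test, p = 1e-05, the smallest that 100000 permutations can give). This permutation ignored runs as well.

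All ARID1A variants fell short of the wild type. Their mean was 19.7% ± 18.1 (SD, n = 12), and all 12 libraries lay below the lowest wild-type library, a difference of -68.7 percentage points (exact permutation test, two-sided, p = 0.000549, adjusted p = 0.00165 over 3 tests). The test treated the libraries as independent, although they are replicates of 6 constructs, so its p-value may be too small. The construct with a mutated ARID domain kept 44.1% ± 2.13 and ARID1A_delIDR1 kept 42.1% ± 1.31 (SD, n = 2 each), a difference within the spread of their libraries. ARID1A_CBR kept 18.4% ± 0.137. ARID1A_DDX4 kept 6.90% ± 0.911, ARID1A_Y42S 4.24% ± 2.85 and ARID1A_AQGscramC1C2 2.30% ± 0.427 (SD, n = 2 each). The values near the background depended on the setting: at equal covered length ARID1A_DDX4 recovered 22.1% and ARID1A_Y42S 18.00%, and with whole lists 0.534% and 1.08%. Each setting scored its own gained regions, which numbered 558 at equal covered length and 17400 with whole lists. The background on those regions is not given here, so these values cannot be placed against it. The ARID1A_Y42S libraries, of unequal list length, recovered 2.23% and 6.26%.

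Within runs A and B, regions gained in one run were scored in the other. ARID1A_WT called 77.1% ± 1.01 of them, ARID1A_DBDmut 41.9% ± 1.2, ARID1A_delIDR1 38.5% ± 0.599, ARID1A_CBR 22.4% ± 0.445 and Empty_vector 6.42% ± 0.667 (SD, n = 2 each). ARID1A_DDX4 and ARID1A_AQGscramC1C2 are alone in their runs, so for them the construct and the run cannot be told apart. ARID1A_Y42S has no control in its run, which it shares with ARID1B_A457_G461del at 78.9%.

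The ARID1B deletions covered the whole range. ARID1B_S320_G327del recovered 93.1% ± 0.546, ARID1B_A457_G461del 78.9% ± 0.866, ARID1B_Block13del 28.5% ± 1.97 and ARID1B_Block9del 3.20% ± 0.746 (SD, n = 2 each), beside 89.8% ± 0.210 for ARID1B_WT. As a group they differed from the wild type by -37.4 percentage points, which did not pass the test (exact permutation test, two-sided, p = 0.103, adjusted p = 0.103). Of their 8 libraries 6 lay below every wild-type library and 2, those of ARID1B_S320_G327del, lay above. Within run C, on regions gained in the other pair of libraries, ARID1B_WT called 78.3% ± 1.14, ARID1B_S320_G327del 76.1% ± 0.0647 and Empty_vector 5.38% ± 2.07 (SD, n = 2 each). The other 3 deletions come from run E, which has no control. Within that run ARID1B_A457_G461del and ARID1B_Block9del differed by 75.7 percentage points.

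**Figure D2:**
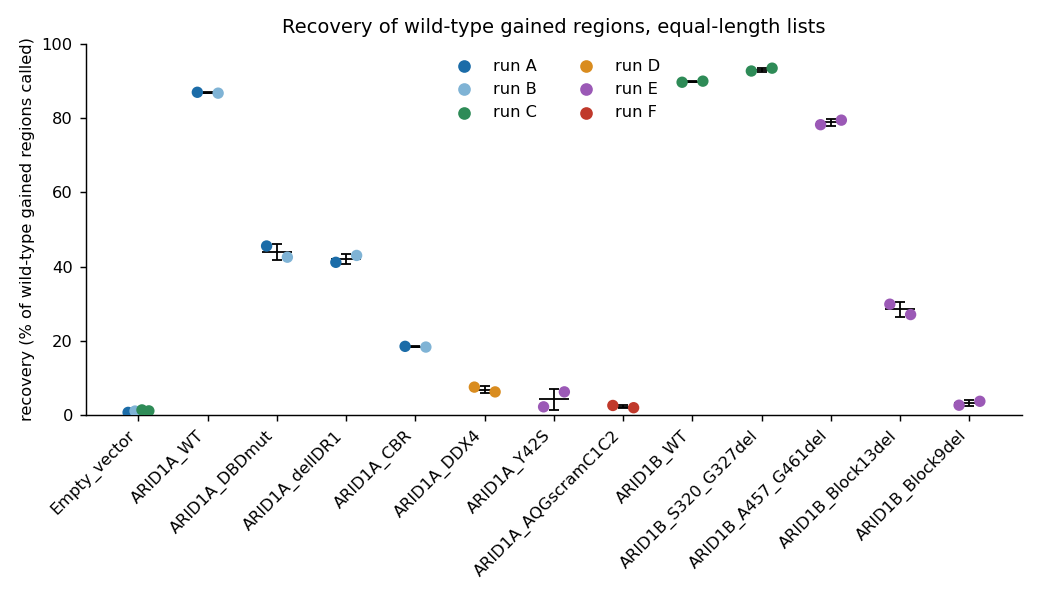
Recovery of wild-type gained regions (vertical axis, percent) for each library, as points coloured by run, with the mean and SD per construct as bars. Wild-type libraries lie near 88.4% and Empty_vector near 1.09%, with the ARID1A variants between 2.30% and 44.1% and the ARID1B deletions between 3.20% and 93.1% on average.

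Against the empty vector, all 20 libraries of altered constructs lay above the highest background of 1.40%. That background is lowered by selection, as the other Empty_vector libraries helped to choose each set, which favours the altered constructs. On the sets gained within runs, Empty_vector called 6.42% in runs A and B and 5.38% in run C. ARID1A_Y42S (4.24%), ARID1B_Block9del (3.20%) and ARID1A_AQGscramC1C2 (2.30%) recovered less than that, but were not scored on those sets. Measured on the sets used for the background, the mean of the 20 libraries was 34.0% ± 32.2 (SD, n = 20), a difference of 32.9 percentage points (exact permutation test, two-sided, p = 0.0427). Here too, replicates of the 10 constructs were treated as independent. The adjusted p over 3 tests was 0.0641, so this comparison failed the correction, and without each Empty_vector library in turn the unadjusted p was 0.0672 to 0.0740. With the replicate number as a block it was 0.124. It was 0.0538 to 0.0621 with whole lists, the shorter lists, a 50% overlap or windows of 500 bp. Single constructs could not be tested below 0.0667, the smallest p of the 15 splits of 2 against 4 libraries, which each of the 10 reached against Empty_vector and against the wild type (exact permutation tests, adjusted p = 0.0667).

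At the deposited threshold the shares could not be lower, since the whole lists contain the trimmed lists. For ARID1A_Y42S 2, whose list sets the equal length, the share stayed at 6.61%. In the whole lists, the libraries called 96.6% ± 0.817 of the 1905 gained regions with ARID1A_DBDmut, 95.8% ± 2.67 with ARID1A_delIDR1, 72.8% ± 10.3 with ARID1A_CBR, 87.5% ± 3.04 with ARID1B_Block13del and 53.2% ± 2.23 with ARID1B_Block9del (SD, n = 2 each). ARID1A_AQGscramC1C2 called 27.6% ± 11.2, ARID1A_Y42S 17.7% ± 15.7 and ARID1A_DDX4 13.9% ± 2.75 (SD, n = 2 each), against 15.0% ± 10.7 in Empty_vector (SD, n = 4). The libraries of these 3 constructs called 19.7% and 35.6%, 28.8% and 6.61%, and 11.9% and 15.8%, and the Empty_vector libraries 4.09% to 25.8%. Each of the 3 thus overlapped the background, with 1 library of ARID1A_AQGscramC1C2 and 1 of ARID1A_Y42S above every Empty_vector library. The Empty_vector shares are lowered by selection, as the gained regions were chosen as absent from their equal-length lists. Comparisons with them at full length therefore favour the constructs.

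**Figure D3:**
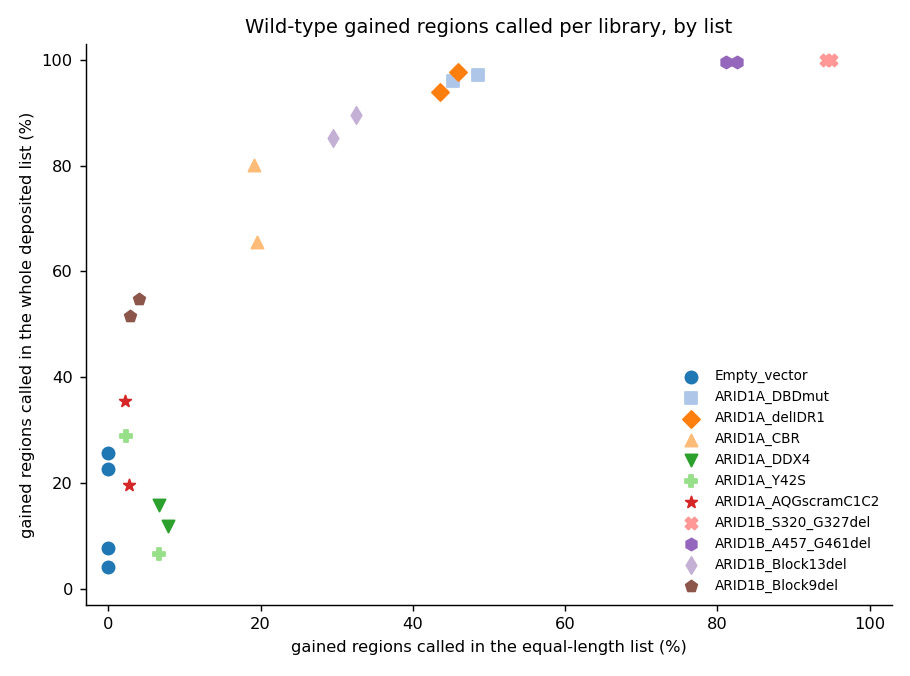
Percent of the 1905 gained regions called by each library in its equal-length list (horizontal axis) and in its whole deposited list (vertical axis), 1 point per library, with the wild-type libraries left out because they define the set. The Empty_vector libraries also define the set, so they lie at 0% on the horizontal axis by definition. ARID1B_Block9del lies low on that axis, at 3.44% on average, but at 53.2% on the vertical axis.

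In lists of equal length, altered constructs called more of the gained regions that were strong in the wild-type libraries. The gained regions were divided into quartiles by their mean rank in the wild-type lists. ARID1A_DBDmut called 73.8% ± 3.85 of the strongest and 27.3% ± 0.594 of the weakest quartile, and ARID1A_delIDR1 called 71.7% ± 0.889 and 24.9% ± 2.82 (SD, n = 2 each). With ARID1A_CBR the shares were 32.6% ± 0.148 and 10.9% ± 0.297, and with ARID1B_Block13del 61.9% ± 3.41 and 9.45% ± 0.297 (SD, n = 2 each). ARID1B_S320_G327del called every region of the strongest quartile and 84.0% ± 1.19 of the weakest (SD, n = 2). These differences by strength were not tested.

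**Figure D4:**
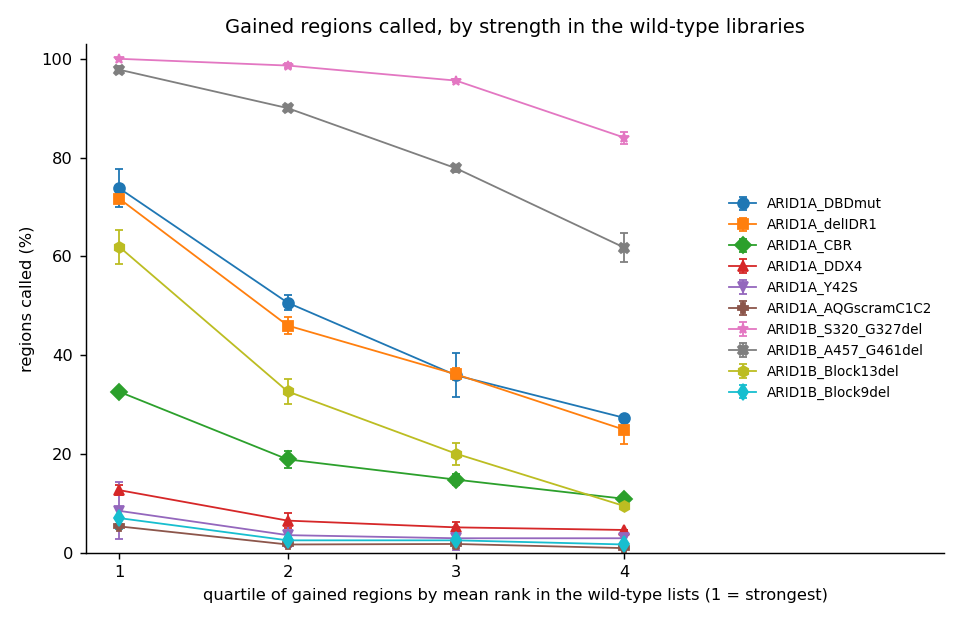
Percent of gained regions called (vertical axis, mean and SD of 2 libraries) by quartile of strength in the wild-type lists (horizontal axis, quartile 1 is the strongest), 1 line per altered construct. In the strongest quartile ARID1B_Block13del lies above ARID1A_CBR (61.9% and 32.6%), and in the weakest they lie close together (9.45% and 10.9%).

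Constructs with low recovery kept more of the lost regions than those with the highest recovery, without an exact reversal of the order. In lists of equal length, ARID1A_AQGscramC1C2 still called 81.5% ± 1.51 of the 750 lost regions, ARID1B_Block9del 73.9% ± 2.73 and ARID1A_CBR 61.5% ± 4.15 (SD, n = 2 each). ARID1B_Block13del called 64.1% in both libraries, although its recovery in these lists was above that of ARID1A_CBR (an order that turned in 3 of the 14 alternatives). ARID1A_DBDmut called 54.5% ± 0.471 and ARID1A_delIDR1 52.5% ± 0.849, ARID1B_A457_G461del 20.9% ± 0.283 and ARID1B_S320_G327del 6.40% ± 1.89 (SD, n = 2 each). In the whole lists this order was gone, with 99.9% ± 0.0943 for ARID1A_CBR, 87.9% ± 2.92 for ARID1B_S320_G327del and 74.7% ± 8.01 for ARID1A_DDX4 (SD, n = 2 each).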

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

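The tests of list length, of runs and of full closure in this part were chosen after the results were seen. The counts of splits were set before the data were examined. The ranking of peaks shared with the empty vector was chosen after seeing the data, but its prediction was set before its outcome was known.

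ARID1B_S320_G327del stood apart from the other ARID1B deletions. On the 2874 regions gained with ARID1A_WT, both of its libraries lay above both ARID1B_WT libraries, at 84.2% ± 1.30 against 73.8% ± 0.172 (SD, n = 2 each), a difference of 10.4 percentage points. All libraries of the other 3 deletions lay below ARID1B_WT on this set. The difference between the deletions was not tested.

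The gain of 1905 regions with the wild-type proteins was given by 1 of the 35 splits of the 8 libraries. That share, 0.0286, is the smallest these splits can give. The splits also treat the libraries as exchangeable, although they come as replicates and in runs, so chance is argued against but not excluded. The highest count of any other split was 83. That other split is the one that parts runs A and B from run C. Longer lists as the whole cause are argued against: the 3 construct libraries of runs A and B with lists no longer than the longest empty vector list called at least 65.6% of the gained regions at full length, against 25.8% in that empty vector list. The latter share is lowered by selection, as the gained regions were chosen as absent from the trimmed list of that library. A difference between runs does not account for it either, since on regions gained in the other pair the wild-type libraries called on average 70.7 percentage points more than the empty vector in runs A and B, and 72.9 in run C. An effect of the expressed wild-type protein remains as a hypothesis, found and tested on the same data.

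The loss of 750 regions was likewise given by 1 of the 35 splits, with 83 as the highest of the others. Full closure of these regions is argued against, since 99.2% of them were called by a wild-type library at full length. Gained peaks may push weaker ones out of a list of fixed length: when only peaks that overlap a peak of any empty vector list were ranked, the count fell to 204, under 50% of the original. The highest count of the other splits was then 113, so part of the loss stays open. At full length, both Empty_vector libraries of runs A and B called 4766 regions that neither ARID1A_WT library called, although the ARID1A_WT lists were longer. In the same runs ARID1A_DBDmut gave 4281 such regions, ARID1A_delIDR1 4162 and ARID1A_CBR 1572. ARID1B_WT gave 500 against the Empty_vector libraries of run C, whose lists are shorter. In lists of equal length the counts were 2278 for ARID1A_WT and 3106 for ARID1B_WT, so the counts at full length cannot be compared between runs.

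For the order of the constructs by recovery, list length as the whole cause is argued against only as far as replicates differ in length. Within constructs, recovery changed by -1.09 percentage points per doubling of the list (SE 2.15), while between constructs the slope was 46.5. Some replicates have lists of similar length, such as ARID1B_Block9del (30137 and 30140 peaks), and some constructs lie near the floor of recovery, so this slope is a weak test. Depth is unknown, so a depth or library quality that differs between constructs was not tested and stays open. Runs as the whole cause are argued against for the constructs that share one. Within run E the means differed by 75.7 percentage points. Within runs A and B the altered constructs lay between 18.4% (ARID1A_CBR) and 44.1% (ARID1A_DBDmut). The range there was 68.4 points with ARID1A_WT, which helps to define the gained regions. In run C, ARID1B_WT and ARID1B_S320_G327del differed by 3.26 points. For ARID1A_DDX4 and ARID1A_AQGscramC1C2 the run and the construct cannot be told apart, as 0 libraries of other constructs share their runs. The level of each protein in the cells was not analysed here and stays open as an explanation for the order.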

How the results depend on the processing

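The leave-out of ARID1A_Y42S 2, the restriction to runs A to C and the ranking of peaks shared with the empty vector were chosen after seeing the data; the other alternatives were not. ARID1A variants lay below the wild type and passed the test under every alternative run. ARID1B variants did not pass the test under any alternative run. Their direction reversed to 4.75 percentage points without the 10 libraries with a conflicting genotype label and in runs A to C alone, because only ARID1B_S320_G327del is left there, and 2 against 4 libraries cannot give a p under 0.0667. The difference of all variants from the empty vector failed the correction already in the main setting, and the alternatives are given by unadjusted p. It was over 0.05 with the whole lists (32.5 points, p = 0.0568), the shorter list (29.7, p = 0.0561), the 50% overlap (28.8, p = 0.0621) and the windows (30.2, p = 0.0538), by exact permutation tests. The difference ranged from 32.3 to 33.1 points without each Empty_vector library. Without each wild-type library it was 31.01 to 31.99 points, with an unadjusted p under 0.05. The gained count moved to 17400 with whole lists, 396 with the shorter list, 558 with equal covered length and 910 when only peaks shared with the empty vector were ranked. In the same order of settings the lost count moved to 79, 119, 89 and 204, and it moved to 332 with the 50% overlap. Whole and shorter lists change the number of peaks by construction, and the cause of the other moves was not tested. Without each wild-type or empty vector library, gained counts were 1919 to 2196 and lost counts 868 to 1029. Leaving out a library removes 1 condition from the same calls, so these counts could not fall. Without ARID1A_Y42S 2, whose list sets the length of all lists, 2258 regions were gained and 905 lost.

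For the constructs of runs A and B the replicate number is also the run, and elsewhere it is a shared number only. The differences between replicates 1 and 2 correlated between constructs of runs A and B, across regions, by -0.0242 to 0.0749 in 10 pairs, never over 0.1. With the replicate number as a block, 1991 regions were gained and 1803 lost, with only Empty_vector 1 and 2 as controls. The blocked differences were -68.7 (p = 0.00128), -37.4 (p = 0.124) and 33.1 points (p = 0.124, exact permutation tests, unadjusted). The last was over 0.05 here even without correction. Location, gene lists, the transgene check and motifs, with their alternatives, were not run, since no hg19 annotation was used here.

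In the 14 alternatives that include them, ARID1B_S320_G327del and ARID1B_A457_G461del kept places 1 and 2 among the 10 altered constructs. Recovery ranged from 35.3% to 55.0% for ARID1A_DBDmut, 34.0% to 54.1% for ARID1A_delIDR1, 14.9% to 25.7% for ARID1A_CBR and 10.1% to 32.3% for ARID1B_Block13del. ARID1B_Block13del fell below ARID1A_CBR with whole lists (23.7% against 25.7%), the shorter list (10.1% against 24.2%) and the 50% overlap (14.7% against 17.3%). Each of these settings scored the regions gained under that setting, not the 1905 of the main setting. On those 1905 regions the whole lists gave the opposite order, 87.5% for ARID1B_Block13del and 72.8% for ARID1A_CBR. The constructs near the background changed places, and recovery ranged from 0.534% to 22.1% for ARID1A_DDX4 and from 0.890% to 18.00% for ARID1A_Y42S. Of such values 75 moved by more than the SD of the libraries of the construct and 70 did not. Unknown depth limits all shares, since a region without a peak can be open below the threshold.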

Other observations

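The regions retained by ARID1A_CBR lay mostly within the larger set retained by ARID1A_delIDR1. Both ARID1A_CBR libraries called 314 of the 1905 gained regions, and 293 of these (93.3%) were among the 718 called by both ARID1A_delIDR1 libraries, where independent choice would give 118, or 147 within quartiles of strength. Such nesting was not particular to this pair. ARID1A_DBDmut held 261 of the 314 (83.1%), with 154 expected within quartiles. The ARID1A_delIDR1 set also held 89.7% of the 78 regions of ARID1A_DDX4 and 96.6% of the 29 of ARID1A_AQGscramC1C2. ARID1B_Block13del called 379 in both libraries, and 374 of these were among the 1447 of ARID1B_A457_G461del, a set so large that 339 would be expected within quartiles of strength. ARID1A_CBR and ARID1B_Block13del shared 108 regions, 34.4% of the smaller set, against 62.5 under independence (Fisher's exact test over regions, adjusted p = 4.82e-11 over 45 pairs) and 88.5 expected within quartiles of strength, a comparison that was not tested. Regions are not independent replicates. ARID1A_CBR, ARID1A_delIDR1 and ARID1A_DBDmut share runs A and B, and ARID1B_Block13del and ARID1B_A457_G461del share run E. ARID1A_CBR and ARID1B_Block13del come from different runs, as do ARID1A_delIDR1, ARID1A_DDX4 and ARID1A_AQGscramC1C2.

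The gained regions were unevenly spread over the chromosomes. Of 23 chromosomes, 10 differed from the rest with an adjusted p under 0.05 (Fisher's exact test over regions), 4 above and 6 below the share of all regions, 5.78%. The highest shares were 10.2% on chromosome 5 (Fisher's exact test, adjusted p = 2.53e-16), 8.86% on chromosome 7, 8.18% on chromosome 10 and 8.05% on chromosome 8. The lowest were 1.16% on chromosome X, 1.83% on chromosome 19 and 1.98% on chromosome 21. For lost regions 0 chromosomes passed. With whole lists, where 18.2% of all regions were gained, the share was 20.4% on chromosome 5, under the 20.6% on chromosome 2 and 20.5% on chromosome 15, which had no excess before. Chromosome 7 then lay below all regions at 17.4%, and chromosome 19 stayed low at 8.77%.

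The test of neighbouring regions and that of read density were set before their outcome was known, and the comparison of chromosomes after. An equal spread of gained regions over open regions is argued against by the 10 chromosomes above. Gained regions may lie in clusters: for 10.7% of them the next region on the chromosome was also gained, against 6.47% on average and 8.88% at most in 10000 shuffles within chromosomes. For lost regions the share was 2.14%, within the range of the shuffles. The 1 Mb windows with most gained regions held 9 each, for example 9 of 31 regions at chromosome 5, 171000001 to 172000000, and 9 of 33 at chromosome 7, 47000001 to 48000000 (hg19). A higher read density on the chromosomes with an excess, as from extra copies, could raise weak peaks into a list of fixed length. Among empty vector peaks of fold 4 to 6, the median -log10 p-value lay above that of the median chromosome in 9 of the 16 pairs of an excess chromosome and an empty vector list, which decides neither way. Relative to the median chromosome it was 0.911 ± 0.0334 on chromosome 8, 1.02 ± 0.0577 on chromosome 5, 1.02 ± 0.0562 on chromosome 10 and 1.04 ± 0.0251 on chromosome 7 (SD, n = 4 each). The highest values were on chromosomes 19 (1.29 ± 0.153), 16 (1.23 ± 0.120), 17 (1.20 ± 0.0846) and 22 (1.13 ± 0.0871), where the share of gained regions, 1.83%, 5.25%, 4.11% and 3.95%, lay below that of all regions. The values of chromosomes 8, 19, 16, 17 and 22 go against the explanation, but the measure may also follow other properties of a chromosome.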
